A study of Mus musculus with 20 samples.

How the data were processed

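RNA levels were measured on 20 mouse Clariom S microarrays, 2 per group in 10 groups. Of these, 8 arrays held cultured cells: per the labels, marrow cells depleted of mature lineages from female wild-type C57BL/6 mice, grown in medium with erythropoietin, with or without interleukin 6 (IL-6) at 100 ng/mL from the start, and collected at points named D1 and D2, which the labels do not define further. The series states that the cultured cells came from 2 wild-type mice. The other 12 arrays held erythroblasts taken from mice aged 1 year, either double wild type (DWT) or double knockout for mDia1 and miR-146a (DKO), at stage I (proerythroblasts), stage II+III (basophilic and polychromatic erythroblasts) and stage IV (orthochromatic erythroblasts). The labels do not state how these stages were isolated. Each genotype had 2 mice. The DWT arrays came from 1 male and 1 female mouse at each stage and the DKO arrays from females. The labels do not tie the DKO arrays of different stages to individual mice. The submitters' notes state amplification of small amounts of total RNA with a Pico kit and no technical replicates.

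The deposited values are log2 signals that the authors made with robust multi-array average (RMA) in Affymetrix Expression Console (versions not given). The notes do not state whether all 20 arrays were normalized together. The range of 2.88 to 19.28 over all arrays matched a log2 scale, and no further transformation was applied. Of 28846 probe sets, 22206 measured transcripts, and 19572 of these carried 1 gene symbol each (19505 genes). The 2634 transcript probe sets without a symbol were kept out of the comparisons. They were tested in a further fit that held them together with the named probe sets. For 55 genes with several probe sets each probe set was tested, and the probe set with the highest mean signal carried the gene's name. Control probe sets (23 background, 1324 positive, 5222 negative and 63 spike-in) served for checks. Signal counted as near background in an array when it lay under the 95th percentile of that array's background probe sets, which ranged from 7.25 to 7.74. Where a gene that passed was near background in both arrays of 1 group only, its log2 fold change is also given as a bound against that level, written "at least" or "bound". No bound is given where only 1 of the 2 arrays lay under that level, which leaves such fold changes less certain, as for Emb, Lgals3, Csf1r, Il6st, Ncf4, Tlr2, Cd48, H2-DMa, H2-DMb1 and H2-Ab1 in D2-Control and Kel, Zfpm1, Slc14a1, Slc43a1, Hemgn, Mfsd2b and Abcb10 in DKO-I. The number of arrays limits the precision, and array signals carry no count depth.

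Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). The 8 cultured arrays were fitted together, with 4 residual and 6.41 prior degrees of freedom, and the 12 in vivo arrays together, with 6 residual and 4.52 prior degrees of freedom. In each fit the groups share 1 estimate of the spread per gene. P-values were 2-sided and Benjamini-Hochberg adjusted over the 19572 probe sets of a comparison, and an adjusted p under 0.05 counted as passing. Errors are standard errors (SE) of the log2 fold change from the fit, with n = 2 arrays per group throughout. Differences of effects between D1 and D2, or between stages, were tested as interaction contrasts in the same fits. Where 1 array of a group is left out, the remaining array of that group is assumed to vary like the other groups.

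Gene lists were tested with camera in limma with a preset correlation of 0.01 and, beside it, with a correlation estimated from the arrays. P-values were adjusted over the 32 lists with at least 4 measured members, separately for each comparison. The 21 pathway lists covered the STAT3 response to IL-6, the JAK2 and STAT5 response to erythropoietin, NF-kB inflammatory genes, miR-146a targets, interferon response, antioxidant genes, NADPH oxidase, haem synthesis, iron handling, erythroid regulators, red cell membrane, cell cycle G2 and M, DNA replication, cytokinesis and formins, autophagy and terminal maturation, p53 and apoptosis, unfolded protein response, ribosomal proteins, cholesterol synthesis, MHC class II and MYC with ribosome biogenesis. The 11 cell type lists covered neutrophils, granulocyte progenitors, monocytes and macrophages, B cells, T and NK cells, megakaryocytes and platelets, mast cells and basophils, eosinophils, stem and progenitor cells, dendritic cells, and stroma with endothelium. Some members are also expressed by erythroid cells or by more than 1 of the other cell types. A globin list with 3 measured members and a list of 3 Y-linked genes were too small to test.

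The genes named for each comparison followed a rule. It took Diaph1, which encodes mDia1, first, then the 10 highest and the 10 lowest log2 fold changes among genes that passed and whose arrays did not overlap between the groups (with fewer than 5 passing, the 5 smallest unadjusted p-values), and from each list up to 4 members that passed. It also took a fixed set as values: Socs3, Alas2, Gata1, Klf1, Tfrc, Slc4a1, Rps14, Tnf, Il6 and Traf6, and Hbb-bt, Hbb-bs, Hba-a1, Irak1 and the miR-146a gene, for which the array had no named probe set. Groups, comparisons, tests, lists, the naming rule and the alternatives were chosen before the data were examined, except where a sentence says otherwise.

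The alternatives were a fit of only the 4 arrays compared, a fit of all 20 arrays, no intensity trend, only probe sets above the array median in at least 2 arrays, quantile normalization once more, centring each array on its median, sex as a term for the in vivo arrays (which separates the DWT mice of each stage), and leaving out each array in turn. Leaving out DKO-I replicate 2 in the comparisons that do not use it was added after the data were seen. The labels do not say which of the 2 mice each cultured array came from, so no fit with the donor as a term was possible, and a fit with the order of the arrays within each group as a term was added after the results were seen. With 2 arrays per group no outlier test within a group was made, and other splits of the arrays were not counted, since 2 arrays against 2 give only 3 splits, too few to be informative.

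The fits were tested on simulated data with 50 changed genes for each of 4 sizes of change. Both compared groups took the mean of the control or DWT group. Independent normal noise had 1 spread per gene, shared by all groups of the fit. In the real arrays the spread within the pair was 0.92 in DKO-I and 0.27 in DWT-I. The simulation holds no array that differs across many genes at once, so its rates do not cover that case. Of genes changed by 1, 2, 3 and 4 on the log2 scale, the IL-6 comparison at D1 recovered 26%, 82%, 96% and 98%, and the DKO comparison at stage I recovered 12%, 50%, 82% and 94%. Recovery was 24%, 82%, 90% and 98% for IL-6 at D2, 10%, 50%, 78% and 96% for DKO at stage II+III, and 14%, 56%, 84% and 94% for DKO at stage IV. No recovered gene had the wrong sign, and between 5 and 11 unchanged genes passed per comparison.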

Results

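The 20 arrays comprised 4 groups of cultured cells (D1-Control, D1-IL6, D2-Control and D2-IL6) and 6 groups of freshly isolated erythroblasts (DWT and DKO at stages I, II+III and IV), with 2 arrays in each group. Between 34.9% and 43.0% of named probe sets lay above background in an array. Arrays of a group correlated at r = 0.97 or more across genes, apart from the DKO-I pair at r = 0.903. DKO-I replicate 2 stood apart from all other arrays: its positive control probe sets had a median of 10.04, against 10.81 to 11.48 elsewhere, and its highest correlation with any array was 0.909. The ribosomal protein gene Rps14 read 12.32 there, whereas the other arrays read 16.0 to 17.3. For some genes the DKO replicates differed at every stage. At stages I, II+III and IV, Kit read 12.26, 14.46 and 12.29 in replicate 1 and 5.76, 10.37 and 6.00 in replicate 2. Other genes lay close, such as S100a8 at 18.50, 17.71 and 15.31 against 17.87, 17.71 and 14.76. Leaving out DKO-I replicate 2 does not address such a difference at the other stages. Red cell membrane genes averaged 14.04 in D1-Control, 14.04 in D2-Control, 12.51 in DWT-I, 13.88 in DWT-II+III and 14.89 in DWT-IV. Neutrophil genes averaged 7.18 in D1-Control and 5.92 in D2-Control, but 15.64 in DWT-I, 11.59 in DWT-II+III and 8.53 in DWT-IV, so the freshly isolated stage I arrays carried strong neutrophil signal.

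**Figure D1:**
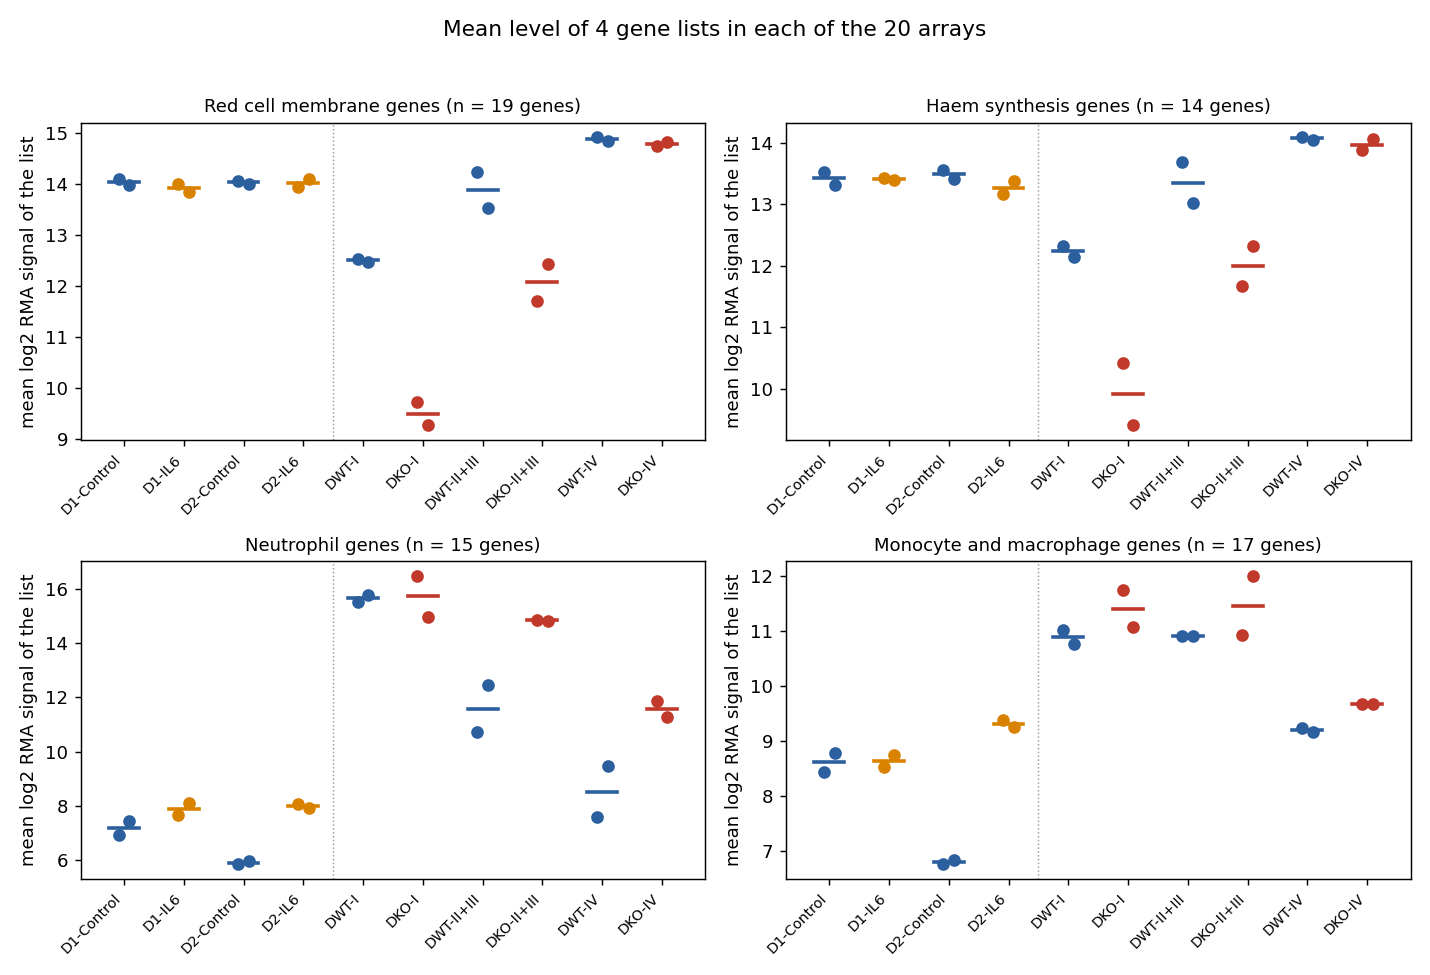
Mean log2 RMA signal of 4 gene lists (y axis) in each array (points) with the group mean (lines), for the 10 groups (x axis), with control and DWT in blue, IL-6 in orange and DKO in red. Red cell membrane genes averaged 9.50 in DKO-I against 12.51 in DWT-I, neutrophil genes 14.83 in DKO-II+III against 11.59 in DWT-II+III, and monocyte and macrophage genes 9.32 in D2-IL6 against 6.81 in D2-Control.

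The comparison of IL-6 with control at D1 asked which transcripts IL-6 changed at the earlier collection point. A few genes rose, among them genes known from granulocytes and from the acute phase response. Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, rose by 4.40 ± 0.28 (adjusted p = 2.95e-04) from a level near background, which bounds the rise at 1.74 or more. Spint1, a membrane serine protease inhibitor, rose by 4.31 ± 0.36 (adjusted p = 0.0019), Hp, the haemoglobin-binding acute phase protein haptoglobin, by 2.69, and Prtn3, a granule protease, by 2.46. The others that rose were Dmkn at 3.37 (at least 1.27), Vcan at 3.18, Il4ra at 1.91, Atp11a at 1.90 (at least 0.79) and Slc2a1, a glucose transporter, at 1.50 ± 0.13 (adjusted p = 0.0022). Axl, a receptor tyrosine kinase of macrophages, fell by 2.47 (at least 0.78).

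In limma 10 genes passed at D1, 9 up and 1 down, and 554 had an unadjusted p under 0.05, where 978.6 would be reached with no effect. Of 11 granulocyte progenitor genes 1 rose over all genes and 5 adjusted over the list alone, with a median of 0.68. Of 15 neutrophil genes 1 rose, and 3 adjusted over the list alone, with a median of 0.36. Of 20 STAT3 genes 1 rose, and 2 adjusted over the list alone. These 3 lists shifted up with adjusted p of 1.1e-09, 1.7e-06 and 9.4e-04, and each had adjusted p = 0.28 with an estimated correlation. Dendritic cell genes shifted down (0 of 10 passing in limma, 2 falling adjusted over the list alone), as did MHC class II (0 of 8), red cell membrane (0 of 19) and erythroid regulators (0 of 19). Their adjusted p was 0.0020, 0.0055, 0.0036 and 0.032, or adjusted p = 0.28, 0.48, 0.54 and 0.35 with an estimated correlation. The haem synthesis gene Alas2 (-0.01), the red cell anion exchanger Slc4a1 (-0.02), Klf1 (-0.12), Gata1 (-0.02), Tfrc (0.00) and Rps14 (0.03) did not pass. Neither did Diaph1 (-0.07), Traf6 (-0.05), Il6 (0.66), Tnf (0.60) or the IL-6 feedback inhibitor Socs3 (-0.06). Tnf was near background in both D1 groups. Socs3 was near background in all 20 arrays, so its values in any comparison do not show whether it responded. The count at D1 was 3 without D1-IL6 replicate 1, 2 without D1-IL6 replicate 2, 4 without D1-Control replicate 1 and 12 without D1-Control replicate 2. Lcn2 and Slc2a1 passed in all 4 of these. The count was 6 after quantile normalization, 2 without an intensity trend, where Slc2a1 did not pass (adjusted p = 0.14), and 0 in limma with all 20 arrays in 1 fit, where Lcn2 had an adjusted p of 0.45. Leaving out arrays in the order given, the shift of erythroid regulators had an adjusted p of 0.051, 0.25, 0.050 and 0.12. Red cell membrane genes had 0.56 without D1-IL6 replicate 2 and 0.33 without D1-Control replicate 1. MHC class II had 0.062 without D1-IL6 replicate 1 and 0.47 without D1-Control replicate 2.

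The comparison of IL-6 with control at D2 asked the same at the later collection point. There genes of monocytes and macrophages were higher with IL-6, with part of the granulocyte genes. A rise here means a level above D2-Control, where some of these genes were lower than in D1-Control. Csf1r averaged 12.03 in D1-Control, 7.24 in D2-Control and 12.87 in D2-IL6, and Ly6c2 14.59, 8.89 and 14.26. Lcn2, in contrast, averaged 4.96, 4.60 and 10.71. The largest rise was that of Mmp8, a neutrophil collagenase, at 8.55 ± 0.40 (adjusted p = 1.2e-06, at least 7.53). Next came Ms4a6d at 7.11 (at least 4.96), Emb at 7.06 ± 0.27, the lectin Lgals3 at 6.91 and Tgfbi at 6.90 (at least 5.65). Spint1 at 6.81 (at least 5.74), Pld4 at 6.7 (at least 5.51), the lysosomal protease Ctsh at 6.55 (at least 5.35), Hp at 6.53 (at least 4.16) and the RNA sensor Tlr13 at 6.28 (at least 3.38) followed. Of 17 monocyte and macrophage genes 10 rose, and 13 adjusted over the list alone. Among them were Csf1r, the receptor of macrophage colony-stimulating factor, at 5.63 ± 0.24 from the background level (7.36 and 7.12 in D2-Control, where background was 7.35 and 7.62), Ly6c2 at 5.37, the pore-forming protein gene Mpeg1 at 5.32 (at least 4.26) and the lysozyme gene Lyz2 at 4.70. That list had a median of 1.79 and an adjusted p of 2.1e-20, or adjusted p = 0.042 with an estimated correlation. Of 5 NADPH oxidase genes, which make the superoxide of phagocytes, 4 rose: Cybb at 5.42, Cyba at 4.90, Ncf4 at 4.51 and Rac2 at 1.17. Their list had an adjusted p of 3.2e-10, or adjusted p = 0.046 with an estimated correlation.

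Some granulocyte genes were also higher with IL-6 than in control at D2. Within the IL-6 cultures Elane averaged 15.75 at D1 and 12.81 at D2, Mpo 15.97 and 11.28, and Prtn3 14.14 and 11.58. With IL-6 too, these 3 genes were thus lower at D2 than at D1. Of 15 neutrophil genes 6 rose, among them Mmp8, Lcn2 at 6.11 (at least 3.22), Wfdc21 at 5.36 (at least 5.28) and Csf3r, the receptor of granulocyte colony-stimulating factor, at 4.52 (at least 2.29), whereas Ngp (0.19), Camp (0.32) and S100a9 (-0.04) did not pass. Of 11 granulocyte progenitor genes 4 rose, the proteases Elane at 3.50, Prtn3 at 2.55 and Ctsg at 1.75 (at least 0.14) and the myeloperoxidase gene Mpo at 1.13. These lists had adjusted p of 4.0e-08 (median 0.26) and 5.3e-04, or adjusted p = 0.16 and 0.22 with an estimated correlation. Antigen presentation genes of MHC class II rose in 5 of 8 cases, with H2-DMb1 at 3.81, H2-DMa at 2.85, H2-Ab1 at 2.64 and H2-Eb1 at 1.63. Their adjusted p was 8.4e-06, or adjusted p = 0.19 with an estimated correlation. Of 26 NF-kB inflammatory genes 6 rose, with the chemokine Ccl3 at 3.10 (at least 1.42), the NF-kB subunit Rel at 3.01 (at least 1.26) and Tlr2 at 1.87 among them. Of 20 STAT3 genes 2 rose, the IL-6 signal transducer Il6st at 3.01 ± 0.31 and Batf at 1.38 (at least 0.99). The NF-kB and STAT3 lists had adjusted p of 0.0012 and 0.0013, or adjusted p = 0.16 and 0.19 with an estimated correlation. Of 14 miR-146a targets 2 rose, and 4 adjusted over the list alone. They were Notch2 at 1.75 and Tnf at 1.59, the second near background in both groups, and the list had an adjusted p of 0.0084, or adjusted p = 0.18 with an estimated correlation. Of 26 cytokinesis and formin genes 7 rose, with Fmnl1 at 3.68 (at least 2.52), a formin of blood cells, Flna at 1.88, which crosslinks actin, and Diaph2 at 1.78 (at least 0.85) among them. Their adjusted p was 5.6e-04, or adjusted p = 0.14 with an estimated correlation.

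Erythroid genes moved little at D2. Haem synthesis genes shifted down by a median of -0.21 (adjusted p = 0.036, or adjusted p = 0.54 with an estimated correlation). Of 14, 1 fell, the mitochondrial iron importer Slc25a37 at -0.51, and 1 rose, Alas1, the non-erythroid form of the first enzyme of the pathway, at 1.40. Erythroid regulators shifted down by a median of -0.20 (adjusted p = 0.030, or adjusted p = 0.22 with an estimated correlation), with Nfia falling (-1.31) and the other 18 members not passing. The red cell membrane list did not shift (adjusted p = 0.30), although Cd44 rose by 1.35 and the blood group gene Kel changed by -0.42. Alas2 (-0.02), Slc4a1 (-0.14), Klf1 (-0.03), Gata1 (-0.58), Tfrc (-0.21) and Rps14 (0.10) did not pass, nor did Diaph1 (0.11), Traf6 (0.38), Il6 (-0.47) and Socs3 (0.11). Alas2, Klf1 and Diaph1 changed sign, near 0, after quantile normalization. Ribosomal protein genes shifted up by a median of 0.12, 53 of 60 positive and 0 passing in limma (adjusted p = 9.7e-07, or adjusted p = 0.30 with an estimated correlation). Of 18 MYC and ribosome biogenesis genes 2 rose, Bop1 at 1.26 (at least 1.21) and Pes1 at 0.98 (adjusted p = 0.042, or adjusted p = 0.48 with an estimated correlation). Single members rose in lists that did not pass. Ifitm3 at 2.07 and Gbp3 at 1.90 (at least 1.2) belong to the interferon list (median -0.07, mean 0.08, adjusted p = 0.57), and Aco1 at 2.08 (at least 1.19) and Fbxl5 at 2.07 (at least 0.35) to the iron list (adjusted p = 0.18). Cd48 at 4.66 and Cd34 at 1.76 (at least 0.94) belong to the stem and progenitor list (median -0.13, mean 0.50, adjusted p = 0.30), and Edem1 at 2.45 to the unfolded protein list (median -0.06, mean 0.15, adjusted p = 0.50). The 10 largest falls were smaller than the rises, from -1.87 for Cnot7, a deadenylase subunit, to -1.39 for Lipf. Between these lay Cd46, Lax1, Pcdh7, Prmt3, Olfr1496, Tssk3, Olfr969 and Dlat, and Olfr1496, Olfr969 and Lipf were near background in both groups.

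In limma 648 genes passed at D2, 571 up and 77 down (88.1% up), of which 101 were near background in both groups, and 2808 had an unadjusted p under 0.05. The split was 549 up and 100 down after quantile normalization, 563 and 64 after centring, and 381 and 7 when only the 4 arrays were fitted. With all 20 arrays in 1 fit 269 passed. The change differed between D2 and D1 for 232 genes by the interaction test, 229 of them higher at D2, among them Lgals3 (6.57 ± 0.69), Csf1r (5.30) and Cyba (4.35). Leaving out D1-IL6 replicate 1 gave 118 such genes, D1-IL6 replicate 2 gave 134 and D1-Control replicate 2 gave 120, and a fit of all 20 arrays gave 54. Of the 10 genes that passed at D1, 8 passed at D2. Among the 648, 475 (73.3%) had the same sign at D1. The counts at D2 were 541, 517, 567 and 557 without each array in turn. The calls of Rac2, Alas1, Batf, Tlr2, Mpo, Ctsg, H2-DMa, H2-Eb1, Bop1, Pes1, Cd44, Kel, Slc25a37, Nfia, Tnf, Gbp3, Fbxl5, Cd34, Flna and Diaph2, and of the largest falls other than Lipf, ended without at least 1 of the arrays D2-IL6 replicate 1, D2-IL6 replicate 2, D2-Control replicate 1 and D2-Control replicate 2. Of the list shifts, STAT3 (0.10), NF-kB (0.053), haem synthesis (0.34) and erythroid regulators (0.19) lost their call without D2-IL6 replicate 1, miR-146a targets (0.068) and MYC (0.51) without D2-IL6 replicate 2, haem synthesis (0.23), erythroid regulators (0.11) and MYC (0.23) without D2-Control replicate 1, and miR-146a targets (0.11) and erythroid regulators (0.089) without D2-Control replicate 2.

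**Figure D2:**
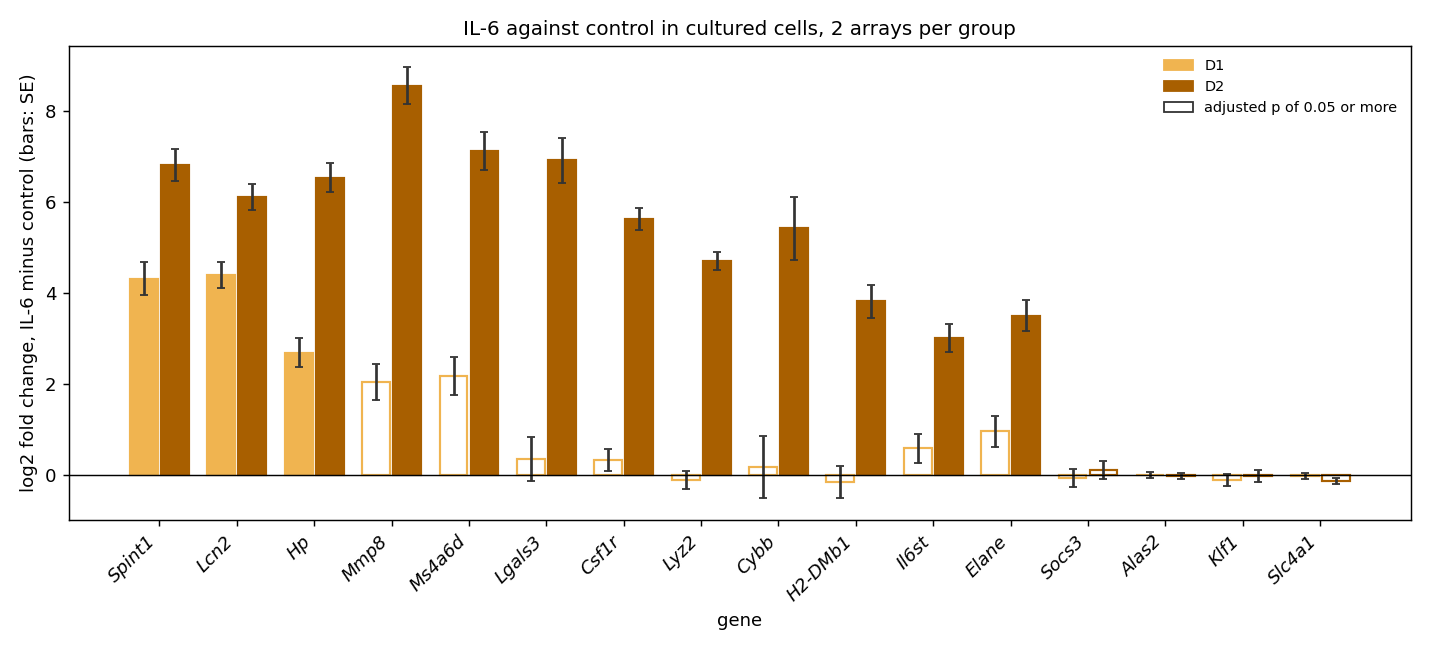
Log2 fold change of IL-6 against control (y axis) at D1 and D2 for 16 genes (x axis), with SE from the limma fit and 2 arrays per group, and filled bars for an adjusted p under 0.05. Mmp8 stood at 8.55 and Csf1r at 5.63 at D2, whereas Alas2, Klf1 and Slc4a1 lay between -0.14 and -0.01 at both points.

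The comparison of DKO with DWT at stage I asked how arrays labelled as proerythroblasts differed with loss of mDia1 and miR-146a. These arrays carried strong neutrophil signal in both genotypes, with S100a8 at 18.00 in DWT-I and 18.18 in DKO-I. Gata1 averaged 8.34 and 7.58, and its 7.16 in DKO-I replicate 1 was near background. A lower share of erythroid RNA and changes within erythroblasts cannot be told apart in the falls below. Diaph1 fell by 3.77 ± 0.42 (adjusted p = 0.0054, at least 3.44) to near background in both DKO arrays. Whether its probe set lies in the deleted part of the gene was not known. Red cell membrane genes were lower in DKO: 12 of 19 fell, and 15 adjusted over the list alone. Among them were Kel at -6.02 ± 0.73, the water channel Aqp1 at -5.98, Epb42 at -4.95, the spectrin gene Sptb at -4.71 (bound -3.52) and Slc4a1 at -3.73 ± 0.32 (adjusted p = 0.0018). That list had a median of -3.36 and an adjusted p of 4.4e-23, or adjusted p = 0.084 with an estimated correlation. Of 14 haem synthesis genes 5 fell, with Alad at -5.38 ± 0.44 (adjusted p = 0.0018), Abcb10 at -3.82, Cpox at -3.39 and Fech at -2.83 among them. Haem synthesis genes had a median of -2.50 and an adjusted p of 1.4e-12, or adjusted p = 0.12 with an estimated correlation. Of 19 erythroid regulators 3 fell, the GATA1 cofactor gene Zfpm1 at -5.58, the erythroid transcription factor Klf1 at -3.33 and the repressor Gfi1b at -2.73. Their median was -1.14 and their adjusted p 8.9e-12, or adjusted p = 0.031 with an estimated correlation.

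Proliferation genes were lower in DKO at stage I by the list tests. In limma 0 of 21 cell cycle genes of G2 and M and 0 of 20 DNA replication genes passed over all genes, and 20 and 18 fell adjusted over the list alone. Their medians were -2.01 and -1.80 (adjusted p = 5.6e-15 and 2.2e-14, or adjusted p = 0.21 and 0.20 with an estimated correlation). Eosinophil genes shifted down by a median of -4.09, with 1 of 7 falling, Il5ra at -3.94 (bound -2.22). That shift had an adjusted p of 4.3e-07, or adjusted p = 0.20 with an estimated correlation. The DKO arrays differed in these groups. Cell cycle genes averaged 12.11 in DKO-I replicate 1 and 9.79 in DKO-I replicate 2, the array that stood apart, against 13.05 and 12.84 in DWT-I. Eosinophil genes averaged 10.80 and 7.30 against 13.24 and 13.14.

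The remaining named falls at stage I included the urea transporter Slc14a1 at -5.54, Slc43a1 at -5.16, Hemgn at -4.98, the sphingosine-1-phosphate exporter Mfsd2b at -4.74 and the nuclear exporter Xpo7 at -4.48. Alas2 fell by 2.39, the erythropoietin receptor Epor by 2.79, Tfr2 by 2.62, the ubiquitin ligase of terminal maturation Ube2o by 2.95 and Odc1 by 3.0. The non-muscle myosin Myh10 fell by 3.69 and the platelet chemokine Ppbp by 3.12. Bounds against background were -2.15 for Epor, -1.30 for Tfr2, -1.94 for Myh10 and -1.57 for Ppbp. The acute phase gene Saa3 rose by 9.79 ± 1.23 (adjusted p = 0.0091, at least 7.74). The T cell gene Cd3g rose by 4.79 (at least 3.96), Il7r by 4.18, Il23r by 3.51 (at least 2.40), Upp1 by 3.29 (at least 1.38) and the complement gene Cfb by 4.23 (at least 1.67). The protease inhibitors Csta2 and Cstdc4 rose by 4.16 and 3.61, Orm1 by 3.11, the Fc receptor Fcgr1 by 2.82 and the chemokine Cxcl2 by 2.26. Neutrophil genes (median -0.14, mean 0.08, adjusted p = 1.00) and T and NK cell genes (median 0.84, adjusted p = 0.061) did not pass as lists. Tfrc (-3.25 ± 0.74), Rps14 (-2.36 ± 1.03), Gata1 (-0.76), Traf6 (-0.78), Tnf (0.38), Socs3 (0.46) and Il6 (-0.47) did not pass. Most of the difference of Rps14 and Traf6 lay in DKO-I replicate 2. Rps14 read 16.88 in DKO-I replicate 1 and 12.32 in replicate 2, against 17.02 and 16.89 in DWT-I. Traf6 read 9.03 and 7.53 against 9.09 and 9.04.

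Another 10 lists shifted down at stage I, and none of these held with an estimated correlation. They were MYC and ribosome biogenesis (median -0.75, adjusted p = 4.2e-06), unfolded protein response (-0.79, 1.0e-04), cytokinesis and formins (-0.63, 3.3e-04), iron handling (-0.73, 5.8e-04) and autophagy and terminal maturation (-0.59, 0.0011). These 5 had adjusted p = 0.21, 0.21, 0.30, 0.20 and 0.15 with an estimated correlation. Then came antioxidant genes (-0.68, adjusted p = 0.0034), the JAK2 and STAT5 response (-0.43, 0.0046), mast cells and basophils (-1.42, 0.0046), cholesterol synthesis (-0.30, 0.017) and granulocyte progenitors (-1.51, 0.029). These had adjusted p = 0.29, 0.30, 0.37, 0.51 and 0.51 with an estimated correlation. The cholesterol shift had an adjusted p of 0.065 without DKO-I replicate 1, 0.061 without DKO-I replicate 2, 0.14 without DWT-I replicate 1 and 0.12 with sex as a term. Without DKO-I replicate 2 the adjusted p was 0.36 for the JAK2 and STAT5 response, 0.30 for antioxidant genes and 0.59 for cytokinesis. Granulocyte progenitor genes turned up in that setting (adjusted p = 0.36). Mast cell genes had an adjusted p of 0.072 without DKO-I replicate 1, and granulocyte progenitor genes 0.057 without DWT-I replicate 1.

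In limma 87 genes passed at stage I, 11 up and 76 down, and 3028 had an unadjusted p under 0.05. The median of all genes was 0.15 higher in DKO, and after centring each array the split was 12 up and 83 down. With sex as a term 24 genes passed (3 up, 21 down, 22 of them among the 87). Saa3, Upp1, Kel, Aqp1, Slc14a1, Alad, Hemgn, Mfsd2b, Sptb, Ppbp, Diaph1 and Slc4a1 (adjusted p = 0.019) kept their call there. The other named genes did not, such as Alas2 (0.13) and Klf1 (0.11). No gene passed in limma without DWT-I replicate 1 or without DWT-I replicate 2, where the adjusted p of Diaph1 was 0.057 and 0.11, nor when only the 4 arrays were fitted. Without the array that stood apart, DKO-I replicate 2, 108 genes passed (16 up, 92 down, 71 of them among the 87). Cd3g, Cfb, Orm1, Cxcl2, Fech, Tfr2, Ube2o, Il5ra and Alas2 no longer passed there. Without DKO-I replicate 1, 6066 passed (3285 up, 2781 down), and with all 20 arrays in 1 fit 502.

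At stage II+III, basophilic and polychromatic erythroblasts, the same comparison shifted the inflammatory and neutrophil lists up in DKO and the erythroid lists down. A minority of their members passed in limma, and of these lists only the erythroid regulators passed with an estimated correlation. Saa3 rose by 8.08 ± 1.23 (adjusted p = 0.017, at least 6.72) and the interleukin 1 family cytokine Il1f9 by 7.43 ± 0.45 (adjusted p = 1.4e-04, at least 5.80). Of 26 NF-kB inflammatory genes 3 rose, Il1b at 4.74 ± 0.49 (adjusted p = 0.0049), its receptor antagonist Il1rn at 4.50 (at least 3.90) and Cxcl2 at 4.21 (at least 3.72). The NF-kB list shifted up by a median of 0.69 (adjusted p = 7.1e-06, or adjusted p = 0.11 with an estimated correlation). Of 15 neutrophil genes 2 rose, the gelatinase gene Mmp9 at 4.94 (at least 3.81) and Wfdc21 at 3.74, and 13 rose adjusted over the list alone. Neutrophil genes had a median of 3.10 (adjusted p = 4.9e-19, or adjusted p = 0.12 with an estimated correlation). Other large rises were the Fc receptor gene Fcgr4 at 5.96, F11r at 5.43 (at least 4.17), Ms4a6d at 5.36 and Dpep2 at 5.17. The lipopolysaccharide coreceptor Cd14 rose by 5.07, Stfa2l1 by 5.04 (at least 3.88) and Smpdl3b by 4.90 (at least 4.30).

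Membrane genes of the red cell fell in 6 of 19 cases at stage II+III, and 14 adjusted over the list alone. Among them were Sptb at -3.80, the tropomodulin gene Tmod1 at -3.40, Dmtn at -3.06, Ermap at -2.92 and Slc4a1 at -2.06 ± 0.32. Their median was -2.25 (adjusted p = 4.4e-15, or adjusted p = 0.11 with an estimated correlation). Erythroid regulators shifted down with 0 of 19 passing in limma and 6 falling adjusted over the list alone (median -1.16, adjusted p = 5.6e-10, or adjusted p = 0.038 with an estimated correlation). Haem synthesis genes shifted down with 1 of 14 falling, Abcb10 at -3.51 (median -1.46, adjusted p = 9.1e-08, or adjusted p = 0.15 with an estimated correlation). Of 18 autophagy and terminal maturation genes 3 fell, Trim58 at -4.29, Ube2o at -3.88 and Atg4a at -2.50. Autophagy genes had a median of -1.49 (adjusted p = 1.5e-07, or adjusted p = 0.038 with an estimated correlation). Diaph1 fell by 3.45 ± 0.42 (adjusted p = 0.0093, at least 3.21). Fcna fell by 5.36 (at least 3.48), Denn2b by 5.05 (at least 2.85), Tmcc2 by 4.56, Sowaha by 4.32, Tbcel by 4.19, Ypel4 by 4.12 and Fam214b by 4.02. Slfn14 and Snx22 each fell by 3.92, Myh10 fell by 3.87 and Cyp11a1 fell by 2.18, with bounds of -2.98 for Snx22 and -0.99 for Cyp11a1. Alas2 (-1.33), Klf1 (-1.15), Gata1 (-0.67), Tfrc (-1.35), Rps14 (0.24), Tnf (2.16), Traf6 (0.52), Il6 (-1.44) and Socs3 (0.08) did not pass.

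Further lists shifted at stage II+III. Up were NADPH oxidase (median 1.56, adjusted p = 1.5e-04), the STAT3 list with Lrg1 rising by 3.86, at least 2.38 (adjusted p = 2.5e-04), ribosomal proteins with 57 of 60 positive (median 0.25, adjusted p = 1.5e-04) and granulocyte progenitors (median 0.63, adjusted p = 0.030). They had adjusted p = 0.32, 0.11, 0.47 and 0.50 with an estimated correlation. Down were cell cycle genes of G2 and M (median -1.18, adjusted p = 1.3e-09), DNA replication (-0.81, 3.6e-05), mast cells and basophils (-2.49, 1.4e-04) and megakaryocytes and platelets (-0.60, 0.020). These 4 had adjusted p = 0.39, 0.47, 0.31 and 0.47 with an estimated correlation. Eosinophil (-1.89, 0.020), stem and progenitor (-1.0, 0.032) and dendritic cell genes (-0.76, 0.034) shifted down too, with adjusted p = 0.47, 0.40 and 0.47 with an estimated correlation. Without DKO-II+III replicate 1 the adjusted p was 0.67 for ribosomal proteins and 0.34 for granulocyte progenitors. Without DKO-II+III replicate 2 it was 0.089 for megakaryocytes, 0.56 for stem cells and 0.56 for dendritic cells, while eosinophil genes turned up (adjusted p = 0.95). Without DWT-II+III replicate 1 it was 0.054 for granulocyte progenitors, stem cells and dendritic cells. Without DWT-II+III replicate 2 it was 0.058 for megakaryocytes, 0.078 for eosinophils and 0.070 for dendritic cells.

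In limma 121 genes passed at stage II+III, 43 up and 78 down, and 1816 had an unadjusted p under 0.05. With sex as a term 15 of these passed (10 up, 5 down), among them Il1f9 (adjusted p = 0.0019), Il1b (0.022), Cxcl2 (0.022), Diaph1 (0.040), Fcna, Denn2b and Tbcel. Saa3 (0.083), Sptb (0.083) and Slc4a1 (0.11) did not pass with that term. The count was 49 without DKO-II+III replicate 2, 5 without DWT-II+III replicate 1 and 54 without DWT-II+III replicate 2. It was 37 when only the 4 arrays were fitted, 547 with all 20 arrays in 1 fit, and 580 (all 121 among them) without DKO-I replicate 2, an array of another stage. Of the named genes, Il1f9 and Fcna passed with each of the stage II+III arrays left out, whereas Saa3 and Fcgr4 passed only without DKO-II+III replicate 1. The adjusted p of Diaph1 was 0.072 without DWT-II+III replicate 1 and 0.060 without DWT-II+III replicate 2.

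At stage IV, orthochromatic erythroblasts, few genes differed between DKO and DWT. Fcgr4 rose by 7.01 ± 0.94 (adjusted p = 0.044, at least 6.46), Il1f9 by 4.22 ± 0.45 (adjusted p = 0.019, at least 2.37), Tmem176b by 3.88 and the myeloid transcription factor Spi1 by 2.80. Fcna (-4.14, bound -2.16), the calcium channel gene Cacna1g (-4.01), Runx1t1 (-3.95, bound -2.76), the pyruvate carboxylase gene Pcx (-2.93) and Lrrc56 (-2.86, bound -1.69) fell. Diaph1 had a log2 fold change of -2.44 ± 0.42 (bound -1.87) and did not pass (adjusted p = 0.10). Neutrophil genes shifted up with all 15 positive, 0 passing in limma over all genes and 11 adjusted over the list alone. Their median was 3.04 (adjusted p = 7.2e-19, or adjusted p = 0.18 with an estimated correlation). Ribosomal protein genes shifted up with all 60 positive (median 0.60, adjusted p = 2.7e-17, or adjusted p = 0.23 with an estimated correlation). The red cell membrane list (median -0.11, adjusted p = 0.64) and the haem synthesis list (median -0.18) did not shift. Alas2 (-0.23), Slc4a1 (-0.39), Klf1 (0.39), Gata1 (-0.46), Tfrc (0.16), Rps14 (0.62), Tnf (0.86), Traf6 (0.61), Il6 (-0.68) and Socs3 (0.08) did not pass.

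Other shifts up at stage IV were those of NF-kB inflammatory genes (median 0.75, adjusted p = 4.7e-05), NADPH oxidase (1.96, 4.7e-05), STAT3 (0.46, 0.0011) and cholesterol synthesis (0.54, 0.0015). These had adjusted p = 0.18, 0.33, 0.18 and 0.54 with an estimated correlation. MYC (0.53, adjusted p = 0.011), unfolded protein response (0.48, 0.012), MHC class II (0.74, 0.029) and miR-146a targets (0.51, 0.047) shifted up as well, with adjusted p = 0.63, 0.59, 0.65 and 0.65 with an estimated correlation. Autophagy and terminal maturation genes (-0.50, adjusted p = 0.0038) and mast cell genes (-0.58, 0.014) shifted down, with adjusted p = 0.18 and 0.62 with an estimated correlation. In limma 9 genes passed at stage IV, 4 up and 5 down, and 1588 had an unadjusted p under 0.05. The split was 1 up and 4 down after quantile normalization. No gene passed in limma with sex as a term, when only the 4 arrays were fitted, or without DKO-IV replicate 1, DKO-IV replicate 2 or DWT-IV replicate 1. In contrast, 124 passed with all 20 arrays in 1 fit, 25 without DWT-IV replicate 2 and 60 (43 up, 17 down, with Diaph1 at an adjusted p of 0.045) without DKO-I replicate 2. The shift of miR-146a targets lost its call without each of the 4 stage IV arrays (adjusted p from 0.074 to 0.15) and with sex as a term (0.054). Unfolded protein genes lost theirs without DKO-IV replicate 1 (0.11) and DWT-IV replicate 2 (0.063). MHC class II genes lost theirs without DKO-IV replicate 1 (0.84), DWT-IV replicate 1 (0.10) and DWT-IV replicate 2 (0.063). Mast cell genes lost theirs without DKO-IV replicate 2 (0.90) and DWT-IV replicate 2 (0.12), and cholesterol genes without DWT-IV replicate 2 (0.21).

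**Figure D3:**
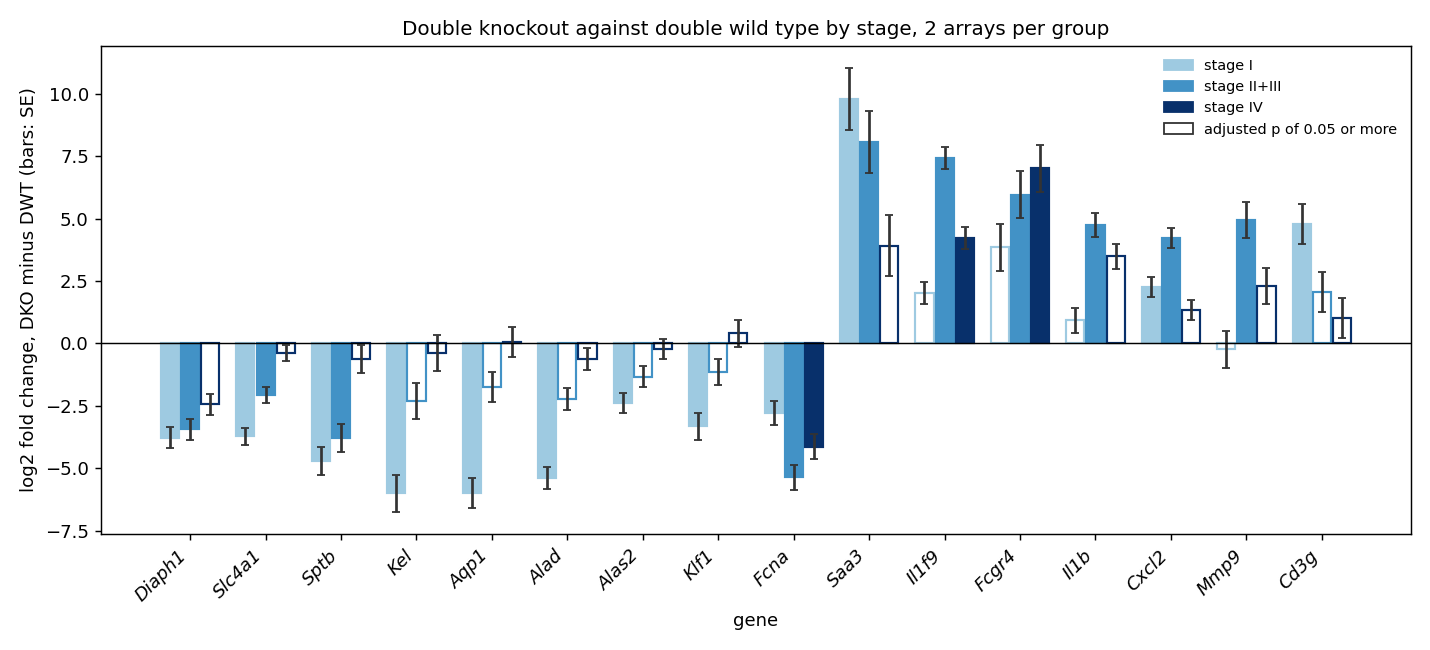
Log2 fold change of DKO against DWT (y axis) at stages I, II+III and IV for 16 genes (x axis), with SE from the limma fit and 2 arrays per group, and filled bars for an adjusted p under 0.05. Slc4a1 stood at -3.73, -2.06 and -0.39 and Il1b at 4.74 at stage II+III, and bars of genes near background in 1 group are not bounds.

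The effects of genotype overlapped between neighbouring stages. With 2 mice per genotype, the stages are not independent repeats of the genotype effect. The genes that passed at both stage I and stage II+III were 33, with 6 up and 27 down in both. At stages II+III and IV they were 5 (Il1f9, Fcgr4, Fcna, Cacna1g and Pcx), and at stages I and IV 1 (Fcna). The fold changes correlated across genes at r = 0.508, 0.585 and 0.193 in that order, and genes are not independent replicates. The difference of the genotype effect between stage II+III and stage I passed for 0 genes in limma, with 942 at an unadjusted p under 0.05. That between stage IV and stage I passed for 0 genes in limma, with 1898 at an unadjusted p under 0.05. For the first, the smallest p-values were those of Il1f9 (5.42 ± 0.64, adjusted p = 0.093), Klra10, Il1b, Mfsd2b and Gstm5, which did not pass. For the second, they were those of Mfsd2b (4.58 ± 0.58, adjusted p = 0.066), Upp1, Alad (4.73), Dmtn and Hemgn, which did not pass either. Without DKO-I replicate 1 the counts were 2700 and 4204, without DKO-I replicate 2 they were 1 and 14, and with all 20 arrays in 1 fit 4 and 49. A single gene passed without DKO-II+III replicate 2 for the first and without DWT-IV replicate 2 for the second. By the list tests the genotype effect on red cell membrane genes was higher at stage IV than at stage I by a median of 2.92 (adjusted p = 3.1e-20, or adjusted p = 0.11 with an estimated correlation). That on neutrophil genes was higher at stage II+III than at stage I by a median of 2.9 (adjusted p = 1.9e-15, or adjusted p = 0.42 with an estimated correlation). Of the lists, 14 passed for the first difference and 17 for the second, and 0 of either with an estimated correlation.

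The IL-6 and DKO effects were set side by side, as the series pairs them, and they share no array. Across genes, the fold changes of IL-6 at D2 correlated with those of DKO at r = 0.03 for stage I (Spearman -0.01), 0.30 for stage II+III (0.22) and 0.37 for stage IV (0.24), and those of IL-6 at D1 at 0.07, 0.18 and 0.15. Of the genes that rose with IL-6 at D2, 10 also rose in DKO at stage II+III, where 1.25 would overlap at random: the pattern receptor genes Cd14, Clec4d and Clec4e, and Saa3, Wfdc21, Ms4a6d, Bst1, Cd300ld, Dpep2 and Lilrb4a. At stage I the overlap was Fcgr1 and Saa3 (0.321 at random) and at stage IV Spi1 and Tmem176b (0.117 at random). These random values treat all named probe sets alike, those near background included. Of the genes that rose, 559 of 571 with IL-6 at D2 and 40 of 43 in DKO at stage II+III were higher in DWT-I than in DWT-IV. Genes of several marrow lineages are higher in DWT-I. The excess at stage II+III therefore does not separate a shared response from RNA of other marrow cells in both comparisons. The correlation of D2 with stage I was 0.24 without DKO-I replicate 2, the array that stood apart, and -0.06 without DKO-I replicate 1. It was -0.04 and 0.09 without D2-IL6 replicate 1 and 2, and 0.01 and 0.05 without D2-Control replicate 1 and 2. That of D1 with stage I was 0.15 without DKO-I replicate 2, 0.03 without DKO-I replicate 1, 0.02 without D1-Control replicate 1 and 0.04 without D1-IL6 replicate 2. With stages II+III and IV, that of D1 was 0.07 and 0.06 without D1-Control replicate 1 and 0.11 and 0.09 without D1-IL6 replicate 2.

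Within wild-type mice, the step from stage I to stage II+III was marked by falling neutrophil genes. This step and the DKO comparison at stage II+III use the same DWT-II+III arrays. The falls here and the rises of the same genes in DKO there, such as Il1f9, Il1b and Mmp9, are therefore not independent measurements. Il1f9 fell by 7.46 ± 0.45 (adjusted p = 1.4e-04, at least 5.83). Of 15 neutrophil genes 5 fell, and 14 adjusted over the list alone, among them Mmp9 at -6.65 (bound -5.53), Mmp8 at -6.28, the chemokine receptor Cxcr2 at -4.51 and Wfdc21 at -3.94. Their median was -3.46 (adjusted p = 8.0e-30, or adjusted p = 0.13 with an estimated correlation). Of 26 NF-kB inflammatory genes 3 fell, Il1rn at -5.24 (bound -4.64), Il1b at -4.07 and Cxcl2 at -3.63 (bound -3.14). That list shifted down (median -0.11, 10 positive, adjusted p = 0.0042, or adjusted p = 0.21 with an estimated correlation). Trem1 at -4.75, Chil1 at -4.71, Slfn4 at -4.66, Cstdc4 at -4.58, Il1r2 at -4.55, Mrgpra2b at -4.54 and Lrg1 at -4.33 fell as well. Bounds against background were -3.80 for Slfn4, -3.48 for Cstdc4, -3.47 for Il1r2 and -2.84 for Lrg1. Membrane genes of the red cell shifted up with 0 passing in limma and 13 of 19 rising adjusted over the list alone (median 1.62, adjusted p = 7.4e-13, or adjusted p = 0.13 with an estimated correlation). Erythroid regulators (1.04, adjusted p = 2.5e-09) and haem synthesis (1.41, 3.3e-07) shifted up too, with adjusted p = 0.058 and 0.20 with an estimated correlation. So did mast cell and basophil genes (2.55, 4.9e-05), T and NK cell genes (2.37, 2.5e-09) and B cell genes (0.66, 0.012), with adjusted p = 0.21, 0.20 and 0.49 with an estimated correlation. The 5 genes that rose were the cadherin gene Cdh1 at 3.0 (at least 2.79), Klra7 at 2.68 (at least 1.89), Olfr67 at 2.22 (at least 0.23), Cyp11a1 at 2.21 (at least 0.90) and Klra10 at 1.83, the last near background at both stages. In limma 48 genes passed, 5 up and 43 down, 1457 had an unadjusted p under 0.05, and 17 of 32 lists shifted, or 0 with an estimated correlation. The count was 7 and 12 without DWT-II+III replicate 1 and 2, and 11 and 4 without DWT-I replicate 1 and 2. It was 911 when only the 4 arrays were fitted, 300 with all 20 arrays in 1 fit and 295 without DKO-I replicate 2. Of the genes named here Il1f9, Slfn4 and Il1r2 passed with each DWT array left out.

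From stage II+III to stage IV in wild-type mice, gene lists of other marrow lineages and of ribosome biogenesis shifted down, while those of the red cell membrane and of haem synthesis shifted up. With an estimated correlation 0 of 32 lists passed. Ribosomal protein genes shifted down by a median of -0.58 (camera adjusted p = 5.7e-09, or adjusted p = 0.30 with an estimated correlation). Their shift up in DKO at stage IV uses the same DWT-IV arrays, so the 2 shifts are not independent measurements. The neutrophil gene S100a8 averaged 18.00, 14.69 and 10.43 in DWT-I, DWT-II+III and DWT-IV, and Gata1 8.34, 9.26 and 11.49. At both steps a changing share of other cells and changes within erythroblasts cannot be told apart. Of 18 MYC and ribosome biogenesis genes 11 fell, with Myc at -4.33 and Srm at -3.81 (median -1.86, adjusted p = 2.7e-10, or adjusted p = 0.16 with an estimated correlation). Of 15 neutrophil genes 8 fell, with Camp at -5.33 and S100a8 at -4.26 (adjusted p = 1.8e-10, or adjusted p = 0.26 with an estimated correlation). Of 17 monocyte and macrophage genes 5 fell, with Csf1r at -3.83 and Lyz2 at -3.49 (adjusted p = 3.3e-06, or adjusted p = 0.16 with an estimated correlation). Of 20 STAT3 genes 3 fell, Il6st at -5.22, the receptor gene Il6ra at -4.02 and Stat3 at -3.57 (median -1.08, adjusted p = 8.2e-05, or adjusted p = 0.16 with an estimated correlation). Of 19 erythroid regulators 4 rose, Gata1 at 2.23, Klf3 at 2.12, Foxo3 at 1.74 and Lmo2 at 1.69, and that list did not shift (median 0.64, adjusted p = 0.21). Haem synthesis genes had a median of 0.85 (adjusted p = 0.012, or adjusted p = 0.38 with an estimated correlation), with Abcb10 rising by 2.27 and Alas1 falling (-4.38). Without DWT-IV replicate 2 and without DWT-II+III replicate 2 the adjusted p of that list was 0.052 and 0.12. The largest rises were Slc25a42 at 3.19, Mgll at 3.15, Smim18 at 3.10 (at least 2.34) and Fntb at 3.03. The red cell membrane list shifted up by a median of 1.14 with Xk rising by 1.88, Add2 by 1.85 and Ermap by 1.61 and Cd44 falling (-2.56; adjusted p = 1.5e-04, or adjusted p = 0.35 with an estimated correlation). Cell cycle genes of G2 and M shifted up by 1.55 with 21 of 21 positive (adjusted p = 2.8e-06, or adjusted p = 0.37 with an estimated correlation). In limma 1010 genes passed, 311 up and 699 down, with the median of all genes 0.12 higher at stage IV, and 4251 had an unadjusted p under 0.05. The split was 446 up and 570 down after quantile normalization, 367 and 606 after centring, and 944 and 1844 when only the 4 arrays were fitted. With all 20 arrays in 1 fit 2465 passed. No gene passed in limma without DWT-IV replicate 1 or without DWT-II+III replicate 2. Without DWT-IV replicate 2, 443 passed, without DWT-II+III replicate 1, 414, and without DKO-I replicate 2, 3272. With sex as a term 688 passed. The calls of Myc, Il6st, Alas1, Foxo3, Lmo2, Xk and Add2 ended without DWT-II+III replicate 1 and also without DWT-IV replicate 2, that of Gata1 without the first of these, and those of Klf3, Abcb10, Ermap and Cd44 without the second.

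Between D1 and D2 the control cultures changed widely, with 4 of 32 lists shifting up at D2 and 11 down (0 with an estimated correlation), those of proliferation among the latter. The nuclear exporter Xpo7 rose by 7.29 ± 0.19, the glucose transporter Slc2a1 by 7.74 ± 0.13, Tmcc2 by 8.28 and Tcp11l2 by 9.42 (at least 8.51). The interferon response genes Rsad2 and Oasl2 rose by 8.85 (at least 6.56) and 7.54 (at least 4.47), Alas2 by 1.98 and Slc4a1 by 0.96. Of 18 autophagy and terminal maturation genes 14 rose, of 18 p53 and apoptosis genes 13 rose, and of 25 interferon response genes 11 rose and 4 fell. These lists had medians of 2.43, 2.63 and 0.61 and adjusted p of 1.6e-10, 1.4e-05 and 0.043, or adjusted p = 0.055, 0.16 and 0.18 with an estimated correlation. All 20 DNA replication genes fell, as did 17 of 18 MYC and ribosome biogenesis genes, 13 of 21 cell cycle genes of G2 and M and all 5 NADPH oxidase genes. Their medians were -2.29, -3.06, -0.96 and -3.12, with adjusted p of 3.1e-14, 1.1e-10, 2.2e-05 and 0.0016, or adjusted p = 0.055, 0.15, 0.29 and 0.16 with an estimated correlation. The stem cell factor receptor Kit fell by 7.47 ± 0.41 (at least 5.62), the mast cell protease Prss34 by 7.45 (at least 6.54), Lgals3 by 6.43 and Emb by 6.21. Red cell membrane (8 of 19 rising, 4 falling, adjusted p = 0.25), haem synthesis (7 of 14 rising, 5 falling, 0.47) and erythroid regulator genes (8 of 19 rising, 9 falling, 0.95) did not shift as lists. Klf1 fell by 0.81 and Rps14 by 0.22, whereas Gata1 (0.29), Tfrc (0.11) and Diaph1 (0.06) did not pass. In limma 8463 genes passed, 3855 up and 4608 down, with the median of all genes 0.17 higher at D2 and 10206 at an unadjusted p under 0.05. The split was 2263 up and 4568 down among probe sets above the array median. The call of Rps14 ended without D1-Control replicate 1 (0.076), D1-Control replicate 2 (0.074) or D2-Control replicate 1 (0.092). That of the interferon list ended without D2-Control replicate 1 (0.062). The stroma and endothelium list did not shift in any comparison (adjusted p = 0.41 here).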

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

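The tests on erythroid, inflammatory and monocyte genes and that on mature neutrophil genes were chosen only after the results were seen, whereas the test of genes carried by the stage I arrays among those raised by IL-6 was set before its value was seen.

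Erythroid genes were lower in DKO at stages I and II+III, by a median of -2.14 and -1.57 over the 52 genes of the haem synthesis, red cell membrane and erythroid regulator lists. The array that stood apart is argued against as the whole cause at stage I, since DKO-I replicate 1 alone lay below DWT-I by a median of -1.87, with 46 of the 52 genes under both DWT-I arrays (replicate 2: -2.56). A shift of the male DWT mouse common to all stages is argued against. With sex as a term the median was -2.10 at stage I and -1.36 at stage II+III. At stage I the red cell membrane list then had a camera adjusted p of 1.7e-22, or adjusted p = 0.12 with an estimated correlation. Erythroid regulators had adjusted p = 2.4e-10, or adjusted p = 0.026 with an estimated correlation. That term is 1 shift shared by the stages. The deviations of the male arrays correlated across genes at only 0.01 to 0.12 between stages. A difference of the male at stage II+III alone is therefore not covered. At stage I the 46 genes of DKO-I replicate 1 lay under the female DWT-I array too. A lower share of erythroid cells with all other cell types raised alike was not settled. At stage I the T and NK cell list (median 0.84) and the eosinophil list (median -4.09) lay 4.93 ± 0.88 apart (SE over genes), or 3.35 ± 0.75 without DKO-I replicate 2. The mean of the first minus that of the second was 5.28 ± 1.54 higher in DKO-I than in DWT-I (SE over arrays). These lists were picked as the highest and lowest of 11 in the same arrays, and genes of a list are not independent. The size of the gap therefore decides nothing, although eosinophil genes were lower and not higher in DKO-I. A change of the genotype in the erythroblasts themselves, and a change in the make-up of the isolated fraction that favours particular cell types, may both contribute and stay open, since arrays of mixed RNA do not separate them and the isolation is not described.

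Neutrophil and NF-kB inflammatory lists were higher in DKO at stage II+III, by medians of 3.10 and 0.69 (adjusted p = 0.12 and 0.11 with an estimated correlation), and the 43 genes that rose, chosen for rising, had a median of 4.09. A shift of the male DWT mouse common to all stages is argued against as the whole cause for the neutrophil list. A difference of the male at stage II+III alone is not covered by a sex term shared by the stages. The median of that list with sex as a term was 2.53 with 15 of 15 positive (camera adjusted p = 2.6e-19, or adjusted p = 0.11 with an estimated correlation). Its SE over genes was 0.31, and the median SE of a single gene was 0.72. The 43 genes had a median of 3.84 with that term (median SE of a single gene 0.60). This decides nothing, since they were chosen in the same arrays and 10 passed. RNA of neutrophils in the isolated fraction stays a candidate source. The genes that rose were higher in DWT-I, where neutrophil genes are high, than in DWT-IV by a median of 4.28, 40 of 43 being higher. The middle 95% of 10000 random gene sets matched on mean level ran from -0.31 to 0.56. Genes of eosinophils and granulocyte progenitors are also higher in DWT-I (13.19 and 13.37, against 8.73 and 9.49 in DWT-IV), so the higher level in DWT-I does not single out neutrophils. Inflammatory expression in the DKO erythroblasts may add to RNA of neutrophils and was not tested separately. The gate or sort that would remove neutrophils is not described in the labels.

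Genes of monocytes and macrophages and some granulocyte genes rose with IL-6 at D2, while the 52 erythroid genes had a median of -0.17. RNA of monocyte or macrophage lineage cells in the culture stays open, since the rise of that list (median 1.79, 16 of 17 higher) is what raised the question and decides nothing. The 571 genes that rose were higher in DWT-I than in DWT-IV by a median of 3.44 (559 of 571). The middle 95% of random sets matched on mean level ran from -0.02 to 0.29. Genes of several marrow lineages are higher in DWT-I, so this does not point to monocytes. For RNA of mature neutrophils, the 5 neutrophil genes with the highest level in DWT-I had a median of 0.32 ± 1.51 at D2 (SE over genes). Their values (Ngp 0.19, Camp 0.32, S100a8 3.42, Lcn2 6.11 and S100a9 -0.04) leave this source open. The cultures began from marrow depleted of mature lineages, a step meant to remove such cells at the start, monocytes and macrophages among them. D1-Control, without IL-6, nonetheless averaged 14.27 for Lyz2, 14.59 for Ly6c2, 14.83 for Mpo and 14.80 for Elane. Of the neutrophil genes, Ngp averaged 9.80 and Camp 6.55 there. The depletion therefore does not argue against myeloid RNA in the culture. A second comparison was chosen after the test of the 5 highest neutrophil genes left mature neutrophils open. It found those 5 genes lower in D2-IL6 than in DWT-I by 7.65 more than the genes that rose (-9.84 against -2.19, a difference of -7.65). The SD among the latter was 1.61, and 2 of the 5 were near background in D2-IL6. This comparison takes DWT-I as the profile of a neutrophil and compares cultured with isolated cells. It also needs a joint normalization that is not stated, so it decides nothing. Expression of these genes in erythroblasts exposed to IL-6, and survival or growth of myeloid cells in the culture under IL-6, may each account for the rise and stay open.

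The effect of IL-6 differed between D2 and D1 for 232 genes by the interaction test in limma. Where the control level fell from D1 to D2, as for Csf1r (12.03 to 7.24), that fall enters the difference. Among the named genes with no group near background in both arrays, the effect at D2 was higher than that at D1 by 6.06 for Emb, 6.57 for Lgals3, 2.43 for Il6st, 1.78 for Notch2, 1.60 for Ifitm3, 5.24 for Cybb, 4.35 for Cyba, 3.24 for Ncf4, 2.16 for Edem1, 3.98 for H2-DMb1, 3.12 for H2-Ab1, 2.55 for Elane, 5.30 for Csf1r, 4.78 for Ly6c2, 4.82 for Lyz2 and 4.25 for Cd48, and the difference was -1.89 for Il4ra and -1.63 for Slc2a1. Of these, Emb, Lgals3, Il6st, Ncf4, H2-DMb1, H2-Ab1, Csf1r and Cd48 had 1 of the 2 D2-Control arrays under background, which leaves the size less certain. For 14 others D2-Control alone lay near background, and the estimate is followed by its bound against that level: 2.50 (1.43) for Spint1, 3.85 (1.47) for Hp, 6.52 (5.49) for Mmp8, 4.94 (2.79) for Ms4a6d, 4.68 (3.43) for Tgfbi, 6.35 (5.15) for Pld4, 6.37 (5.17) for Ctsh, 5.41 (2.51) for Tlr13, 3.90 (2.22) for Ccl3, 2.54 (0.79) for Rel, 2.77 (1.62) for Fmnl1, 3.72 (3.64) for Wfdc21, 4.01 (1.77) for Csf3r and 5.26 (4.21) for Mpeg1. For Axl (4.26), Nlrp3 (3.61) and Lipf (-1.63) 3 or all 4 groups lay near background, so the size of the difference has no bound.

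Probe sets without a gene symbol, which the comparisons leave out, were fitted and adjusted together with the named probe sets. Of 2634, 64 passed for IL-6 at D2, 5 for DKO at stage I, 12 at stage II+III and 1 at stage IV.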

How the results depend on the processing

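Leaving out DKO-I replicate 2 in the comparisons that do not use it, leaving out arrays for the correlations, and array order as a replicate block were chosen after the data were seen; the other alternatives were planned. With 2 arrays per group, counts moved widely while directions mostly held. Of the tests of named genes, 2937 kept their direction and side of the threshold in settings other than leaving out an array, 413 kept the direction and no longer passed, 15 newly passed and 4 reversed, and with 1 array left out these were 1573, 709, 21 and 21. Of the list shifts these were 280, 191, 0 and 0, and with 1 array left out 689, 95, 0 and 4. Only lists that had passed were counted, so none could newly pass. Signal near background limits the fold changes given as bounds.

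With all 20 arrays in 1 fit the counts of genes were 0 for IL-6 at D1, 269 at D2, 502, 547 and 124 for DKO at stages I, II+III and IV, 300 and 2465 for the DWT steps, 54 for the IL-6 difference between D2 and D1, and 4 and 49 for the DKO differences between stages. With only the 4 arrays compared they were 388 for IL-6 at D2, 0, 37 and 0 for DKO at the 3 stages, and 911 and 2788 for the DWT steps. Without an intensity trend 2 genes passed for IL-6 at D1, 6 for DKO at stage IV and 1 for the difference between stages II+III and I. After quantile normalization 6 passed for IL-6 at D1, 5 for DKO at stage IV and 5 for the difference between stages IV and I. With sex as a term 24, 15 and 0 passed for DKO at the 3 stages. With an estimated correlation 0 lists passed for IL-6 at D1, 2 at D2, 1, 2 and 0 for DKO at the 3 stages, 0 and 0 for the DWT steps, 0 for D2 against D1, 1 for the IL-6 difference and 0 and 0 for the DKO differences. With only brighter probe sets 4 lists passed for IL-6 at D1, and r was 0.21 for IL-6 at D1 with DKO at stage IV and 0.37 and 0.43 for D2 with stages II+III and IV; with sex as a term r was -0.013, 0.25 and 0.32 for D2 with the 3 stages. Except for the fits with fewer arrays, the cause was not tested. With the order of the cultured arrays as a replicate block 4 genes passed for IL-6 at D1, 558 at D2, 8113 for D2 against D1 and 199 for the IL-6 difference, and 9, 13, 17 and 9 lists. That order need not follow the donor: the deviations of the first arrays correlated at 0.13 between the D1 groups, -0.15 between the D2 groups and -0.06 to 0.00 across them.

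Leaving out 1 array at a time gave 2 to 12 genes for IL-6 at D1, 517 to 567 at D2, 0 to 6066, 5 to 580 and 0 to 60 for DKO at the 3 stages, 4 to 295 and 0 to 3272 for the DWT steps, 5735 to 7701 for D2 against D1, 118 to 230 for the IL-6 difference, and 0 to 2700 and 0 to 4204 for the DKO differences. The lists that passed were 5 to 8, 9 to 12, 14 to 21, 15 to 18, 7 to 14, 14 to 18, 19 to 21, 13 to 17, 7 to 11, 11 to 18 and 17 to 23 in that order. The correlations were 0.022 to 0.149, 0.066 to 0.228 and 0.056 to 0.193 for IL-6 at D1 with the 3 stages and -0.062 to 0.24, 0.208 to 0.344 and 0.285 to 0.382 for D2, with -0.036 for D2 and stage I without D2-IL6 replicate 1.

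Genes whose value reversed had not passed, whereas the lists that reversed had, and the cause was not tested. For IL-6 at D2 after quantile normalization Alas2 was 0.0011, Klf1 0.0039 and Diaph1 -0.044, and for DKO at stage I with sex as a term Il6 was 0.20. Leaving out 1 array at a time, the values for IL-6 at D1 ran from -0.0062 to 1.33 for Il6, -0.080 to 0.068 for Alas2, -0.092 to 0.049 for Slc4a1, -0.049 to 0.042 for Tfrc, -0.27 to 0.23 for Gata1, -0.55 to 0.42 for Diaph1 and -0.15 to 0.024 for Socs3. For IL-6 at D2 they ran from -0.062 to 0.029 for Alas2, -0.13 to 0.066 for Klf1, -0.052 to 0.28 for Diaph1, -0.26 to 1.02 for Traf6, -1.15 to 0.21 for Il6 and -0.0063 to 0.23 for Socs3. For DKO they ran from -0.56 to 1.31 for Tnf at stage I, -0.082 to 0.56 for Rps14 at stage II+III and -0.96 to 0.043 for Gata1 at stage IV. Among lists the adjusted p ran from 9.8e-04 to 0.36 for granulocyte progenitors at stage I, where the direction turned without DKO-I replicate 2, and from 2.0e-05 to 0.95 for eosinophils at stage II+III, where it turned without DKO-II+III replicate 2. For the difference between stages II+III and I it ran from 1.2e-08 to 0.37 for G2 and M genes and from 2.2e-04 to 0.64 for cytokinesis genes, and both turned without DKO-I replicate 2 (adjusted p = 0.0061 and 0.64).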

Other observations

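The alternatives quoted here were planned, and the genes of the first paragraph were chosen after their values were seen.

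The myeloid genes Csf1r and Lyz2, which IL-6 raised at D2, were lower in the control cultures at D2 than at D1. Csf1r averaged 12.03 in D1-Control, 7.24 in D2-Control and 12.87 in D2-IL6, and Lyz2 14.27, 10.14 and 14.83. Both comparisons use the D2-Control arrays, so the fall and the rise are not independent measurements.

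The mean neutrophil signal of the isolated arrays was lower at each later stage in the DWT groups. In DKO it was lowest at stage IV, while members differed in direction between stages I and II+III. Camp averaged 17.50 in DKO-I and 17.96 in DKO-II+III and Ngp 18.41 and 18.47, but S100a8 18.18 and 17.71 and Ltf 15.79 and 14.80. Differences between the DKO stages were not tested. Neutrophil genes averaged 15.72 in DKO-I, 14.83 in DKO-II+III and 11.56 in DKO-IV, and 15.64, 11.59 and 8.53 in the DWT groups. Eosinophil genes averaged 13.19 in DWT-I and 9.05 in DKO-I, 12.25 and 10.58 at stage II+III, and 8.73 and 7.90 at stage IV. T and NK cell genes averaged 7.21 in DWT-I, 9.50 in DWT-II+III and 7.85 in DWT-IV, and 8.35, 9.86 and 8.12 in the DKO groups.

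From D1 to D2 in control cultures, 44 of 60 ribosomal protein genes fell and 2 rose (median -0.39, adjusted p = 1.3e-10, or adjusted p = 0.18 with an estimated correlation). Of 18 unfolded protein response genes 11 rose and 3 fell (median 0.94, adjusted p = 0.0012, or adjusted p = 0.17 with an estimated correlation). Monocyte and macrophage genes fell in 9 of 17 cases (median -1.33, adjusted p = 0.0015, or adjusted p = 0.16 with an estimated correlation), MHC class II genes in 5 of 8 (adjusted p = 0.0026, or adjusted p = 0.28 with an estimated correlation) and cholesterol synthesis genes in 7 of 15 (adjusted p = 0.040, or adjusted p = 0.46 with an estimated correlation). The cholesterol shift had an adjusted p of 0.083 without D1-Control replicate 1 and 0.078 without D2-Control replicate 1.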
